A study of Solanum lycopersicum with 24 samples.

How the data were processed

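Tomato fruit RNA was profiled for N1-methyladenosine (m1A), a methylated form of adenosine, by immunoprecipitation of fragmented RNA with an m1A antibody followed by sequencing. The series holds 24 samples: 12 immunoprecipitated (IP) libraries and 12 input libraries. They come from the wild type Ailsa Craig (AC) and the ethylene receptor mutant Never-ripe (Nr), 2 genotypes each sampled at 2 stages with 3 replicates. The stages are mature green, approximately 39 days post-anthesis, and 6 days after breaker (Br+6). The titles call the Nr groups G and O. They were taken as the green and the late stage, since the series design describes late Nr fruit as orange.

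Per the labels' protocols, input and IP RNA were both treated with alkali to rearrange m1A to m6A and then made into whole-RNA libraries. The submitters' processing notes name cutadapt 1.9.3 and HISAT2 2.0.4. The peak caller's settings and the control used for each peak list are not given in the sources used here; peak names in the lists begin with MACS. The data used were 36 peak lists, 12 for each of mRNA, lncRNA and circRNA. Each list was assigned to its IP library by the genotype, stage and replicate number in the name the authors gave it. The input libraries have no list of their own and were not analysed here.

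The deposited fold enrichment is a ratio made by the authors' peak caller, and its highest value is 50. The deposited score of a peak equals 10 times the negative log10 of its p-value per the file headers. The deposited FDR column is a percent per the file headers and reads 100 for every peak in all 36 lists, so it was not used as a filter. Peak length as deposited is the end minus the start. Fold enrichments were not tested between libraries. They ordered genes within lists, set the median threshold and the equal list lengths of the alternatives, and described how strong recurrent peaks were. Sequencing depth is unknown, because the lists hold no read totals, so no interval or floor based on depth is given. P-values of tests on libraries cover the spread between these libraries. Fisher tests with genes as units, such as the overlap test, do not, as genes are not independent replicates.

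A peak was counted once per library. An mRNA gene was counted as called in a library when at least 1 peak of that library's mRNA list lay in it. Identifiers come from the transcript column, as the gene-name column sometimes holds a symbol. Coordinates are 1-based on SL3.00, the assembly named by a scaffold in the circRNA lists, and for a gene give the span of its listed peaks. The reference table given for names is of another assembly, SLM_r2.1, so none of its coordinates were used. Of 1945 mRNA genes called, 974 had a description in the lists and 968 an NCBI gene number. Of those numbers, 964 were found in the reference table and 948 had the same symbol there. Names such as E8, VI and CNR belong to identifiers written into the gene lists beforehand and were not checked against a reference. The position of peaks within exons, introns or UTRs was not analysed here for want of a matching annotation.

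Peak numbers were compared as means of log2 numbers with two-sided exact permutation tests. A comparison of 3 against 3 libraries has 20 arrangements and a smallest p of 0.1. Tests pooled over both genotypes or both stages exchanged labels within the other factor, which gives 400 arrangements and a smallest p of 0.005. The 21 peak-number tests were adjusted together by the Benjamini-Hochberg method. A gene was called gained or lost in a comparison when it had a peak in at least 2 of 3 libraries of one group and in 0 of 3 of the other, with no test per gene. Genes called in 3 to 9 of the 12 libraries were tested one by one for stage and for genotype with a two-sided Fisher exact test of 6 against 6. Agreement between libraries was the mean Jaccard index of gene sets within groups minus that between groups, with a one-sided permutation test of 100000 draws. Overlap of AC and Nr changes was tested with the two-sided Fisher exact test.

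Of 13 gene lists fixed beforehand, 12 could be built from identifiers and words in the descriptions. The list of organelle-encoded genes had no members, since no peak lay on an organelle sequence. For each list with at least 5 members called in any library, the percent of a library's called mRNA genes in the list was compared by the same stratified exact test and adjusted over 7 lists. These were ethylene synthesis and signalling, ripening regulators, cell wall and softening, sugar and starch metabolism, photosynthesis and chloroplast, cytosolic ribosomal proteins and translation (the translation list), and heat shock and chaperones. The lists for carotenoid synthesis (2 members called), histones (3), RNA modification (4), lipoxygenase and volatile synthesis (4) and seed tissue markers (0) were too small to test. Word matching also took in a few unrelated genes, such as TFIID subunit 2 in the translation list.

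Genes to be named were fixed by a rule before the data were examined. The rule took, per comparison, up to 10 genes per direction, first those with 3 of 3 against 0 of 3 and then those with 2 of 3, ordered by fold enrichment. It added up to 4 gained or lost members of each list, the 10 genes called in most libraries, and NR, RIN, NOR, CNR, PSY1, PG2A, ACS2, ACO1 and E8 whatever their calls. For lncRNAs and circRNAs it took at most 3 per direction. The text prints a selection of these, mostly genes with a name, and says where a gene was chosen outside the rule.

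The per-gene test was tested on simulated calls for 1945 genes, 200 of them changed. With call rates of 0.1 against 0.9 it recovered 34.5% of the changed genes for stage and 31.5% for genotype. With rates of 0 against 1 it recovered 100% for both, with 3 false calls for stage and 1 for genotype. These recoveries do not carry over to the data. The simulation tested 515 to 527 genes with 200 changed, while 140 genes were tested in the data. With 140 genes, a single gene called in all 6 libraries of 1 side only could not pass the adjustment alone. Alternatives planned beforehand were peaks at or above the median fold enrichment of their RNA class, genes in place of peaks, raw in place of log2 numbers, a replicate block, 3 of 3 against 0 of 3 libraries, merged peak regions in place of genes, lists cut to equal length by fold enrichment, other filters, tests, indices and backgrounds, and leaving out each library in turn. Another 4 were added after the data had been seen: leaving out the 2 longest lists together, leaving out genes called in all 12 libraries, removing TFIID and chloroplast members from the translation list, and keeping only peaks of 100 bases or more. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.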

Results

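The data are lists of m1A peaks in mRNAs, lncRNAs and circRNAs for 12 IP libraries of tomato fruit. The libraries form 4 groups of 3 replicates: AC MG and AC Br+6 (wild type, green and red ripe) and Nr G and Nr O (Never-ripe mutant, green and late, when its fruit is orange). Together the lists held 3852 mRNA peaks, 46 lncRNA peaks and 434 circRNA peaks, summed over libraries. The number of mRNA peaks per library ranged from 108 to 854, with a median of 234.5. Sequencing depth is unknown. Fold enrichments below are the authors' values.

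**Figure D1:**
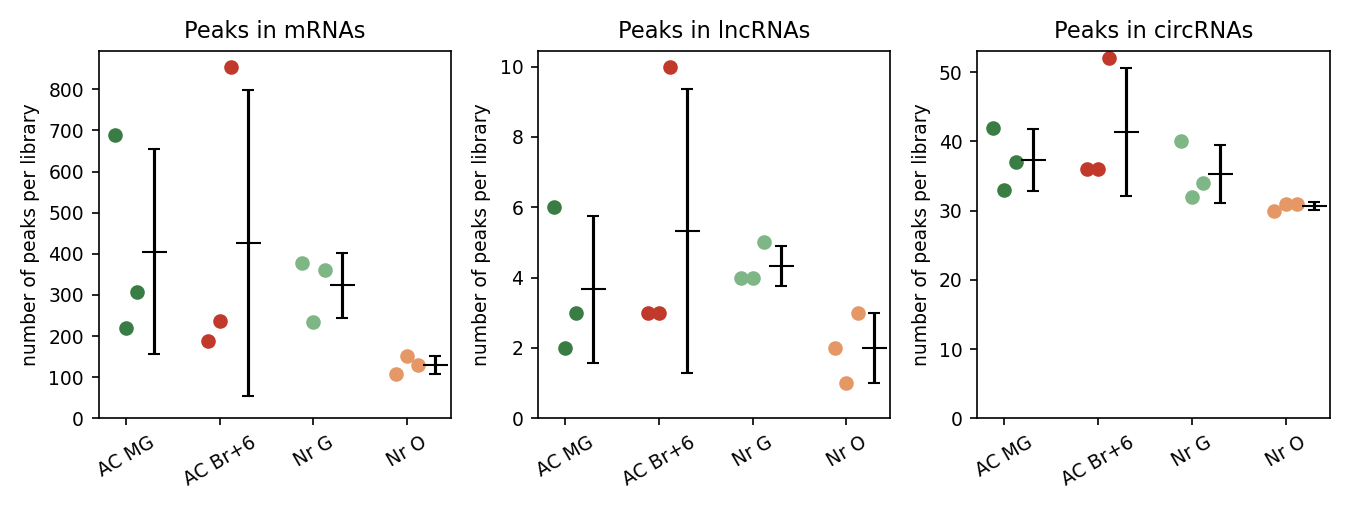
Number of peaks per library (y axis) in mRNAs, lncRNAs and circRNAs for the 4 groups (x axis). Points are libraries and bars show mean ± SD (n = 3); the 3 Nr O libraries had 108, 151 and 129 mRNA peaks, below every other library.

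Which transcripts carried m1A peaks in every library was asked first. ASR1 (Solyc04g071610), described in the lists as a fruit-ripening protein, had peaks in all 12 libraries on chromosome 4 between 58664498 and 58665932. A UDP-arabinopyranose mutase gene (Solyc02g065740) was called in all 12 at the highest fold enrichment the lists allow, 50, on chromosome 2 from 37458387 to 37458772. The gene for a BRISC and BRCA1-A complex member (Solyc04g081500, chromosome 4, 65539155 to 65539307) and that for a cytochrome b-c1 complex subunit 8 (Solyc06g007540, chromosome 6, 1519353 to 1519616) were called in all 12 as well. So was a homolog of the twinkle protein (Solyc02g022830, chromosome 2, 24617673 to 24618062). In all, 61 of 1945 genes (3.14%) were called in every library, and 14 of the 61 had a description. Of these 61 genes, 29 had a peak with the same start and end in all 12 libraries. At the other end, 1471 genes (75.6%) were called in 1 library and 257 in 2. ASR1 was chosen after its values were seen, as were the fruit-specific gene 2A11 (Solyc07g049140), called in 9 libraries, and a peroxidase gene (Solyc02g090450), called in 10.

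**Figure D2:**
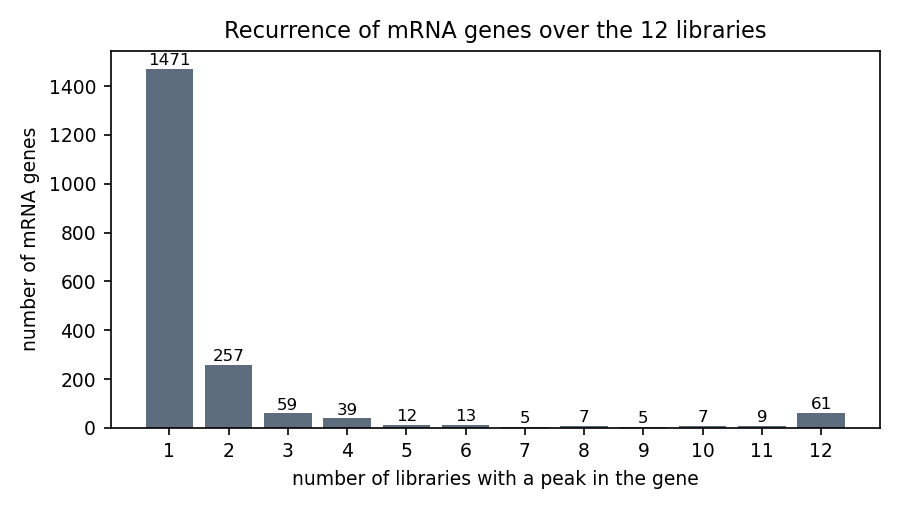
Number of mRNA genes (y axis, bars) by the number of libraries, of 12, in which the gene had a peak (x axis). Most genes, 1471, stood at 1 library, and 61 stood at 12.

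Of the 9 ripening genes fixed for naming whatever their calls, 4 had no peak. NR (Solyc09g075440, the receptor gene mutated in Never-ripe), RIN, NOR and ACS2 had a peak in 0 of 12 libraries. The ripening gene E8 (Solyc09g089580) had peaks in 2 of 3 AC MG and 2 of 3 AC Br+6 libraries and in 0 of 6 Nr libraries. ACO1 (Solyc07g049530), which encodes the enzyme of the last step of ethylene synthesis, and the ripening regulator CNR (Solyc02g077920) each had peaks in 2 AC MG libraries, 1 AC Br+6 library and 0 of 6 Nr libraries. Phytoene synthase 1, PSY1 (Solyc03g031860), had peaks in 1 library of each AC group and 0 of 6 Nr libraries. The polygalacturonase gene PG2A (Solyc10g080210) had a peak in 1 AC MG, 1 AC Br+6 and 1 Nr O library.

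**Figure D3:**
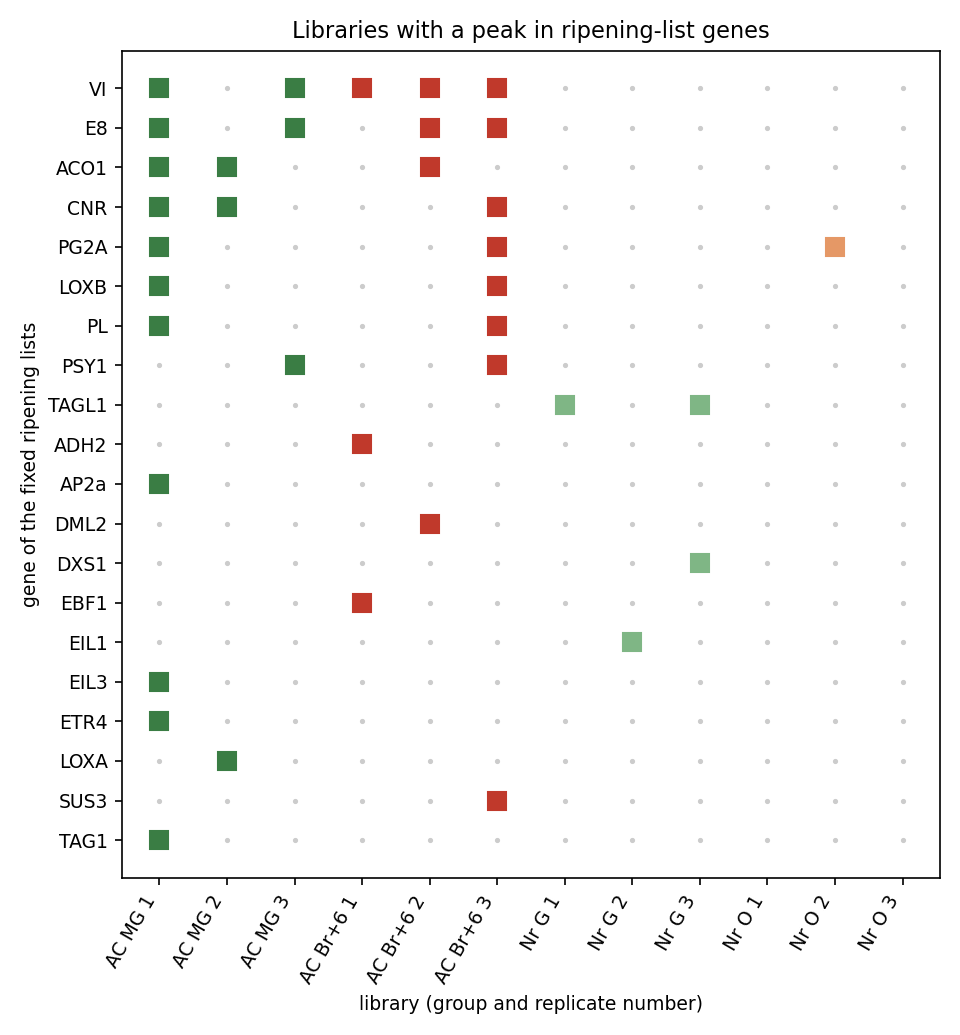
Libraries (x axis) with a peak (coloured square) or without (grey dot) in 20 genes (y axis), the called ones of 64 fixed by identifier in 6 gene lists tied to ripening. Members found by description words are not shown, and some had a peak in Nr G, such as a cellulose synthase gene (Solyc01g087210). VI had a peak in 5 of 6 AC libraries and 0 of 6 Nr libraries, and 4 of the 20 genes shown, PG2A, TAGL1, DXS1 and EIL1, had a peak in Nr.

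Wild-type fruit at the red ripe stage was compared with wild-type green fruit to ask which mRNAs gain or lose m1A peaks during normal ripening. The gene for an early light-inducible protein, ELIP (Solyc09g082690, chromosome 9, 68835185 to 68835521), a cytochrome P450 94A1-like gene (Solyc09g066150) and a heat shock cognate 70 kDa gene (Solyc11g066100) were among 20 gained genes, each called in 2 of 3 AC Br+6 and 0 of 3 AC MG libraries. Lost genes numbered 28. They included the alcohol acyl transferase gene AAT2 (Solyc03g025320, chromosome 3, 2786895 to 2787288) and a thiamine thiazole synthase gene (Solyc07g064160), each called in 2 of 3 AC MG and 0 of 3 AC Br+6 libraries. The ribosomal protein genes for S8 (Solyc06g007570) and L32-1 (Solyc02g070310) and a YTH-domain gene (Solyc01g103540) were lost in the same way. Of the lost genes, 2 (Solyc10g051390 and Solyc11g011390, with no description) were called in 3 of 3 against 0 of 3, and no gained gene was. For a gene called in 3 of the 6 libraries, chance puts all 3 in 1 group with a share of 10%. Mean mRNA peak number was 405 ± 249 (SD, n = 3) in AC MG and 426 ± 371 (SD, n = 3) in AC Br+6. The log2 difference was -0.10 ± 0.84 (SE), with a two-sided exact permutation p of 0.9 (adjusted p 0.9 over 21 tests), less than the spread between replicates. Without AC Br+6 replicate 3, which had 854 peaks, 1 gene was gained and 52 were lost. Without AC MG replicate 1, which had 688, 31 were gained and 4 lost. With a library left out, here and below, its group had to show 2 of 2 calls or 0 of 2. Such shifts therefore follow in part from the rule.

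The same comparison in Never-ripe asked what remains when ethylene perception is impaired. A polyubiquitin gene (Solyc07g064130, chromosome 7, 66536088 to 66538155) was called in 3 of 3 Nr G libraries and 0 of 3 Nr O libraries. The aquaporin gene PIP1-5 (Solyc08g081190), the chaperone genes HSC80 (Solyc07g065840) and HSC70-2-like (Solyc09g010630), and the MADS-box gene TAGL1 (Solyc07g055920) were each called in 2 of 3 Nr G and 0 of 3 Nr O libraries. So were the genes for ribosomal proteins S24 (Solyc09g065330) and L27a-3 (Solyc06g071720) and for elongation factor 1-alpha (Solyc06g005060). In total 53 genes were lost, 4 of them with 3 of 3 against 0 of 3. Only 5 were gained, among them genes for ATP synthase subunit d (Solyc11g072450) and a root-isoform phosphatidylinositol 3-kinase (Solyc04g015350). The gained gene with 3 of 3 against 0 of 3, Solyc11g071640, had no description. Mean mRNA peak number was 323 ± 78.7 (SD, n = 3) in Nr G and 129 ± 21.5 (SD, n = 3) in Nr O. The log2 difference was -1.30 ± 0.26 (SE), 2.47-fold fewer in Nr O, and every Nr O library lay below every Nr G library. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows, with an adjusted p of 0.315 over 21 tests. With lists cut to equal length, 34 genes were gained and 9 lost, but 32 of the 34 had a peak in Nr G in the full lists, so their gain came from shortening the lists. Without Nr G replicate 1, 5 were gained and 11 lost.

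Green fruit of both genotypes was compared to ask whether the mutant differs at the green stage. Whether ripening had begun in any AC MG fruit was not tested. E8, ACO1, CNR and the vacuolar invertase gene VI (Solyc03g083910, chromosome 3, 55280603 to 55283499) were each called in 2 of 3 AC MG and 0 of 3 Nr G libraries. AAT2 and a gene for translation initiation factor 3 subunit B (Solyc01g088370) showed the same calls. In the other direction, TAGL1, a bZIP transcription factor 60 gene (Solyc04g082890), the gene for rubisco accumulation factor 1.1 (Solyc11g006060) and an NDR1/HIN1-like gene (Solyc01g007220) were called in 2 of 3 Nr G and 0 of 3 AC MG libraries. In total, 42 genes were called in at least 2 of 3 AC MG and 0 of 3 Nr G libraries, 5 of them with 3 of 3 against 0 of 3. The reverse held for 24 genes, with 0 at 3 of 3 against 0 of 3. The mRNA peak numbers differed by a log2 value of -0.19 ± 0.54 (SE), Nr G minus AC MG, with a two-sided exact permutation p of 0.9 (adjusted p 0.9 over 21 tests). Without AC MG replicate 1 the counts turned to 9 and 39.

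Late fruit of both genotypes was compared to ask what separates red wild-type from orange mutant fruit. VI was called in 3 of 3 AC Br+6 and 0 of 3 Nr O libraries. E8, the cytochrome P450 94A1-like gene, the heat shock cognate 70 kDa gene Solyc11g066100 and a QWRF7-like gene (Solyc01g096840, chromosome 1, 87717792 to 87717808) were called in 2 of 3 AC Br+6 and 0 of 3 Nr O libraries. In all, 41 genes were called in at least 2 of 3 AC Br+6 and 0 of 3 Nr O libraries, 5 of them with 3 of 3 against 0 of 3. The reverse held for 2 genes, the phosphatidylinositol 3-kinase gene Solyc04g015350 and Solyc03g121880. The log2 difference in mRNA peak number, Nr O minus AC Br+6, was -1.39 ± 0.69 (SE), 2.62-fold fewer in Nr O. Its two-sided exact permutation p was 0.1, the smallest possible, with an adjusted p of 0.315 over 21 tests. With lists cut to equal length the counts became 9 and 23, but all 23 had a peak in AC Br+6 in the full lists. Without AC Br+6 replicate 3 they were 8 and 5. Leaving out 1 library at a time, the log2 difference in mRNA peak number ran from -1.81 to -0.717, the last without AC Br+6 replicate 3.

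Over both genotypes, the mRNA peak number differed between late and green fruit by a log2 value of -0.70 (two-sided exact permutation p 0.165, adjusted p 0.347). Over both stages, Nr minus AC was -0.79 (p 0.105 by the same exact test, adjusted p 0.315). It ran from -0.998 without AC Br+6 replicate 1 to -0.452 without AC Br+6 replicate 3. The stage effect in Nr minus that in AC was -1.20 (p 0.235 by the exact test, adjusted p 0.449), so the genotypes were not shown to differ in it. That value ran from -1.67 without AC MG replicate 1 to -0.530 without AC Br+6 replicate 3. None of the 21 peak-number tests passed after adjustment, and none had an unadjusted p under 0.05. Those of 3 against 3 libraries could not pass, and a pooled test at its smallest p could not pass alone.

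Single genes were then tested over all 12 libraries, 6 against 6. VI differed most by genotype, with peaks in 5 of 6 AC and 0 of 6 Nr libraries (two-sided Fisher exact p 0.0152, adjusted p 0.979 over 140 genes). Adjusted over the list alone, 1 gene of the sugar and starch list passed, and VI was the 1 member tested. That pass was lost with stronger peaks or equal list length, where the lowest exact p of any gene was 0.0606 and 0.182. No member of another list passed when adjusted over the list alone, for stage or genotype. Of the 140 genes, 0 passed the adjusted Fisher exact test for genotype, where 1 had an unadjusted p under 0.05. For stage 0 passed as well, 0 had an unadjusted p under 0.05, and the lowest p was 0.0606. A single gene called in all 6 libraries of 1 side only could not pass this adjustment alone. The counts of 0 therefore do not show that no gene differs.

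Groups of genes with shared functions were compared as a percent of each library's called genes. Genes of the translation list fell from 2.91% of called genes in green fruit to 1.68% in late fruit. The group means were 3.05% ± 0.353 (SD, n = 3) in AC MG, 2.33% ± 0.033 in AC Br+6, 2.77% ± 0.258 in Nr G and 1.02% ± 0.894 in Nr O. Of its 57 members called in any library, 31 were called in AC MG, 25 in AC Br+6, 20 in Nr G and 4 in Nr O. Members with peaks in 3 of the groups included the genes for ribosomal proteins S2-4 (Solyc04g074300) and L29 (Solyc05g053440), both chosen after their values were seen. The difference, -1.23 percentage points, had a two-sided exact permutation p of 0.005, the smallest possible, and an adjusted p of 0.035 over 7 lists. Within each genotype all 3 late libraries lay below all 3 green ones. This was the 1 list of 7 that passed for stage, and it did not pass when only peaks at or above the median fold enrichment were used (-1.03, adjusted p 0.385) or when lists were cut to equal length (-0.767, adjusted p 0.933). It also did not pass without the genes called in all 12 libraries (-1.14, adjusted p 0.21). Without the 2 longest lists its adjusted p was 0.117 (-1.13), but too few arrangements were left there for 1 list to pass alone. Both alternatives were chosen after seeing the data. The genes called in all 12 libraries made up a mean of 21.2% of called genes in Nr G and 50.8% in Nr O.

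By genotype, 0 lists passed the adjusted exact permutation test, and 2 had an unadjusted p under 0.05. Ethylene genes, 9 of them called in any library, made up 0.603% of called genes in AC and 0.0765% in Nr (two-sided exact permutation p 0.01, adjusted p 0.07 over 7 lists). Their calls included EIL3 and ETR4 in AC MG, EBF1 in AC Br+6 and EIL1 in Nr G, each in 1 library and chosen after their values were seen. Translation genes made up 2.69% in AC and 1.89% in Nr (p 0.02 by the same exact test, adjusted p 0.07). Heat shock and chaperone genes, 32 called in any library, had a mean of 1.94% ± 0.224 (SD, n = 3) in AC Br+6 and were called in 0 of 3 Nr O libraries (genotype difference -0.94 percentage points, exact permutation p 0.07, adjusted p 0.14). None of the genes called in all 12 libraries was in this list, and they made up a mean of 24.2% of called genes in AC Br+6 and 50.8% in Nr O. The 0 in Nr O thus rests on 43, 80 and 60 other genes per library. Photosynthesis genes, for instance CAB3A and RBCS-1 (chosen likewise), were called mostly in Nr G, 7 of 9 members, 5 of them in replicate 1, with a genotype difference of 0.372 percentage points (exact permutation p 0.17, adjusted p 0.21). Ripening regulators (5 called; -0.168, adjusted p 0.21), cell wall genes (7 called; -0.171, adjusted p 0.35) and sugar and starch genes (6 called; -0.336, adjusted p 0.14) did not pass either. Among lists too small to test, the RNA modification genes included the demethylase gene SlALKBH2 (Solyc01g104130), called in 1 Nr G library and likewise chosen after its calls were seen. Without AC MG replicate 3, 3 lists passed for genotype. With 2 unrelated members removed from the translation list, a choice made after seeing the data, 2 lists passed, and the translation list had an adjusted p of 0.035.

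**Figure D4:**
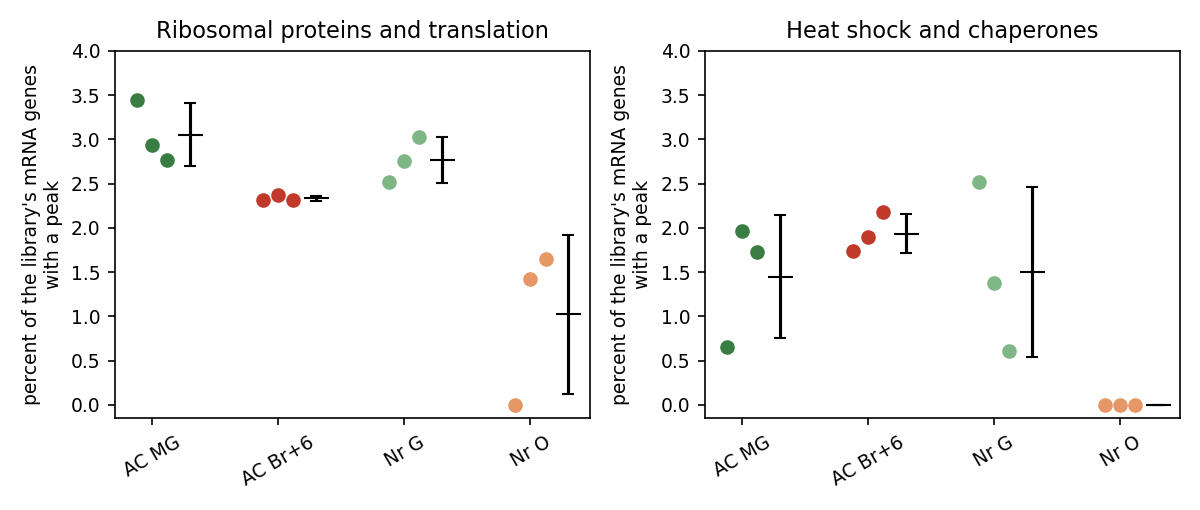
Percent of a library's called mRNA genes (y axis) that belong to the translation list and to the heat shock and chaperone list, by group (x axis). Points are libraries and bars show mean ± SD (n = 3). The translation list averaged 1.02% in Nr O against 3.05% in AC MG. No heat shock gene was called in Nr O, whose libraries held 43, 80 and 60 genes beyond those called in all 12 libraries.

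Libraries of the same group shared more called genes than libraries of different groups. The mean Jaccard index was 0.273 over 12 pairs within groups and 0.229 over 54 pairs between groups, a difference of 0.0447 (one-sided permutation p 0.0162). The difference rested on Nr O, whose pairs ranged from 0.497 to 0.552. The within-group means of AC MG (0.182), AC Br+6 (0.181) and Nr G (0.212) lay below their means with other groups (0.212, 0.225 and 0.217). The overlap coefficient in place of the Jaccard index gave a difference of -0.0295. Without Nr O replicate 1, 2 or 3 the Jaccard difference was -0.000521, 0.00604 or 0.000936. Of the 28 genes lost in AC ripening and the 53 lost in Nr ripening, 2 were shared (Solyc07g045440 and Solyc12g039030), against 3.13 by chance (two-sided Fisher exact p 0.757). Gained genes shared 0.

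In circRNAs, 10 of 38 circles had peaks in all 12 libraries, and these held 346 of the 434 peaks (79.7%). The circle on chromosome 11 from 18750703 to 18845571 alone held 151 peaks (34.8%). Circles hosted by genes named for ribosomal RNA held 132 peaks (30.4%). This share goes by host name, not by position. The span of the chromosome 11 circle above overlapped that of a circle with such a host on the other strand (18797378 to 18869388). So did the span of another chromosome 11 circle (18796389 to 18868400), which held 20 peaks. The span of a circle with host PG2 (chromosome 10, 61691834 to 61722625) had a peak in all 12 libraries, which lay at Solyc10g080260, a gene with an mRNA peak in all 12; this circle and the next were chosen after their values were seen. A circle with host ACO1 (chromosome 7, 59958636 to 59974996) had peaks in 2 AC MG libraries, 1 AC Br+6 library and 0 of 6 Nr libraries. Its peaks were the same as those listed for the ACO1 mRNA (Solyc07g049530). A total of 211 circRNA peaks (48.6%) were also listed as mRNA peaks of the same library, so both lists count the same signal there. The share of circRNA peaks whose host gene also had an mRNA peak ran from 3.33% (95% Clopper-Pearson interval 0.0844 to 17.2, counting error only) in Nr O replicate 1 to 33.3% (19.6 to 49.5) in AC MG replicate 1. Mean circRNA peak number was 37.3 ± 4.51 (SD, n = 3) in AC MG, 41.3 ± 9.24 in AC Br+6, 35.3 ± 4.16 in Nr G and 30.7 ± 0.577 in Nr O. Over both stages the log2 difference, Nr minus AC, was -0.24 (two-sided exact permutation p 0.06, adjusted p 0.315 over 21 tests).

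Among lncRNAs, Solyc06g011490 (chromosome 6, 7606869 to 7609087) had a peak in all 12 libraries and Solyc02g032360 (chromosome 2, 28839381 to 28840102) in 8. A total of 14 lncRNAs had a peak, 6 of them in 1 library. Mean lncRNA peak number was 3.67 ± 2.08 (SD, n = 3) in AC MG, 5.33 ± 4.04 in AC Br+6, 4.33 ± 0.577 in Nr G and 2 ± 1 in Nr O. The log2 difference between Nr O and Nr G was -1.25 ± 0.48 (SE), with a two-sided exact permutation p of 0.1, the smallest possible, and an adjusted p of 0.315 over 21 tests.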

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

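The comparison of peak numbering, both tests on genes called in every library and the test on ripening genes were chosen after the results they measure had been seen.

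Heat shock and chaperone genes stood out because their stage effect differed between genotypes: the effect in Nr minus that in AC was -1.99 percentage points (two-sided exact permutation p 0.02). Adjusted over the 10 such differences tested, p was 0.2, so it did not pass.

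The numbers in the peak names had gaps, so the lists may not hold all called peaks. A median of 72.4% of the numbers up to the highest one listed, over 12 libraries, stood in none of the 3 lists. What those numbers stood for, and where any such peaks lay, was not analysed here.

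Nr O had fewer mRNA peaks than Nr G, a log2 difference of -1.30 that did not pass its test. If all called peaks had fallen in proportion, the highest peak number would be lower by as much. Its difference was -0.21 ± 0.24 (SE), which argues against a fall in proportion. It does not decide on a technical shortfall, since mRNA peaks varied more than the highest number between replicates too. AC Br+6 replicates 1 and 3 had 188 and 854 mRNA peaks but highest numbers of 933 and 1651. Weak peaks missing from Nr O and short fragments in Nr G were argued against. The difference was -1.26 among peaks at or above the median fold enrichment and -1.31 among peaks of 100 bases or more. The percent of peak numbers in no list was higher in Nr O by a log2 value of 0.31 ± 0.08 (SE). That percent rises whenever listed peaks fall more than the highest number. Mean listed peaks were 345 in Nr G and 150 in Nr O, and mean highest numbers 1000 and 872. It therefore cannot show that called peaks fell outside listed genes. A library-wide shortfall of peaks or called peaks outside listed genes may account for the pattern, and neither was decided. So may a difference in input coverage or a change in methylation late in Nr fruit, and neither was tested.

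The 61 genes called in all 12 libraries formed the next pattern. Loci named for ribosomal RNA were near few of them, as 5 genes (8.20%, 95% Clopper-Pearson interval 2.72 to 18.1) had a peak within 100 kb of a circle with such a host. Of the 1471 genes called once, 0 had such a peak (two-sided Fisher exact p 8.5e-08, with genes as units). Most of the 61 genes lay away from the 7 circles with such a host. Ribosomal RNA sequence elsewhere could not be seen, so the share does not decide this explanation. Recurrence may follow the strength of the peak, since the median fold enrichment of these genes was above that of the other genes in 12 of 12 libraries, yet 13 of the 61 had a mean fold below the median of all mRNA peaks. No biological explanation was tested.

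The 64 genes fixed by identifier in 6 ripening lists, leaving out members found by description words, were called more often in AC (mean 5.33 ± 3.39, SD, n = 6) than in Nr (0.833 ± 0.753, SD, n = 6). The difference was -4.50, with the smallest two-sided exact permutation p possible, 0.005. Without AC MG replicate 1, where 11 were called, it was -3.17 (exact permutation p 0.01). Tests of a mislabelled AC MG library were dropped, as their outcome was fixed by calls already seen. Longer AC lists as the whole cause were argued against, since as a percent of genes called in under 12 libraries the difference was -1.50 percentage points (exact permutation p 0.01). With lists of equal length few such genes were left, 1.17 ± 1.17 (SD) in AC and 0.167 ± 0.408 in Nr, and the difference of -1 gene did not pass (exact permutation p 0.15), while the ratio of the means was 6.4 before and 7 after. An effect of the mutation on these transcripts' level or methylation, or a difference in input coverage, may account for the pattern, and neither was tested. The lists were pooled, and the way to judge the outcome was set and later changed, after these values had been seen: judged by the size of the difference with equal list length as well, longer lists had stayed open, and an earlier form on genes picked because they had peaks had favoured them.

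For genes gained and lost, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 48 genes against 118 at most in other splits for ripening in AC, where 8 of 10 splits, the real one included, gave as many. The 4 splits that put the 2 longest lists on the same side gave 87 to 118 and the other splits at most 59. The count thus followed list length, as 2 long lists on 1 side give more genes with 2 calls there. It does not show a structure of the samples apart from list length. The Jaccard index of these 2 lists was 0.156, against 0.159 for AC MG replicate 1 and Nr G replicate 3. The real split gave 58 against 40 for ripening in Nr, 66 against 70 for genotype in green fruit (3 splits as large, the real one included), and 43 against 31 for genotype in late fruit. In Nr ripening, the splits with the longest lists, Nr G replicates 1 and 3, on the same side gave 31 to 58 and the others at most 22. For genotype in late fruit, those with AC Br+6 replicates 2 and 3 together gave 27 to 43 and the others at most 26. Every Nr O list was shorter than every Nr G and AC Br+6 list, so group and list length cannot be told apart there. For single genes tested 6 against 6, the real split and each of the 100 splits drawn gave 0 genes past the adjusted Fisher exact test for stage and for genotype. With 0 in the real split every other split gives as many, so this count decides nothing. At an unadjusted p under 0.05 the real splits gave 0 and 1 genes, and other splits at most 4.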

How the results depend on the processing

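Alternatives chosen after seeing the data were leaving out the 2 longest lists, leaving out genes called in all 12 libraries, trimming the translation list and keeping peaks of 100 bases or more; the causes of the shifts given here were not tested. Over 284 alternative peak-number tests, 0 passed after adjustment (lowest adjusted p 0.245). The position of peaks in transcripts was not run, for want of a matching annotation, and unknown depth limits every count.

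With peaks at or above the median fold enrichment, the lncRNA stage difference turned to 0.36 and circRNA ripening in AC to -0.25. Gained genes then numbered 11, 2, 8 and 0 for ripening in AC, ripening in Nr, genotype in green and genotype in late fruit, and lost genes 17, 22 and 17 for the last 3. No gene list passed for stage (0 of 7), and the genotype difference of cell wall genes turned to 0.021. Counting genes, circRNA ripening in AC was -0.14. As raw numbers, mRNA ripening in AC was 20.7 peaks higher. Requiring 3 of 3 against 0 of 3 left 0 gained and 2 lost, 1 and 4, 0 and 5, and 0 and 5. With equal list length the counts were 13 and 18, 34 and 9, 13 and 23, and 23 and 9, where 32 of the 34 and all of the last 23 had a peak in the other group in the full lists, and 0 lists passed for stage. Of 87 named gene and comparison pairs, 40 kept their calls with equal list length and 42 with stronger peaks; none turned.

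The overlap coefficient in place of the Jaccard index turned the agreement to -0.0295. With genes of 1 call or more as background, the 2 shared lost genes lay above chance in place of below it (two-sided Fisher exact p 0.176).

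Replicate numbers did not pair the libraries, as 0 of 18 same-number correlations were over 0.1 (highest 0.0722). With the replicate number as a block, mRNA ripening in Nr kept its log2 difference of -1.30 (exact p 0.25, the smallest 3 pairs allow), and 0 lists passed for stage. The translation list then had an exact p of 0.0313, the smallest possible, and an adjusted p of 0.219, so it could not pass alone. The lowest exact p of any gene for genotype was then 0.0625, the smallest that 5 differing pairs allow. Neither says anything about stability.

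Without the 2 longest lists, the mRNA genotype difference in green fruit turned to 0.28. Gained and lost genes were 6 and 11 for ripening in AC, 39 and 9 for genotype in green and 5 and 8 for genotype in late fruit. Each AC group was then judged on 2 of 2 or 0 of 2 libraries. The ethylene stage difference turned to 0.096, and 0 lists passed for stage, though 1 list could not pass alone with so few arrangements. That count was also 0 without genes called in all 12 libraries. The adjusted p of the translation list ran from 0.035 to 0.933 over all its alternatives for stage. With 2 unrelated members removed from it, 2 lists passed for genotype.

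Leaving out 1 library at a time, gained and lost genes ran from 1 to 31 and 4 to 52 for ripening in AC, 1 to 9 and 11 to 59 for ripening in Nr, 5 to 39 and 9 to 50 for genotype in green fruit, and 0 to 5 and 8 to 46 for genotype in late fruit. AC MG replicate 1, AC Br+6 replicate 3 and Nr G replicate 1 set most of these limits. Log2 differences that changed sign were mRNA ripening in AC (-0.77 to 0.37) and genotype in green fruit (-0.54 to 0.28), lncRNA ripening in AC (-0.14 to 0.87), and circRNA ripening in AC (-0.045 to 0.22), genotype in green fruit (-0.17 to 0.0095) and stage (-0.12 to 0.013). Agreement ran from -0.000521 to 0.0701, lost without any 1 of the Nr O libraries. Shared lost genes ran from 0 to 5. For stage, list differences that changed sign were ethylene (-0.167 to 0.0142), cell wall (-0.0509 to 0.155) and sugar (-0.019 to 0.205), and the translation list passed each time. For genotype, 0 to 3 lists passed, the 3 without AC MG replicate 3.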
